A study of Arabidopsis thaliana with 24 samples.

How the data were processed

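Messenger RNA levels were measured by RNA sequencing of adult leaves of Arabidopsis thaliana in 24 libraries that formed 8 groups of 3. The groups crossed the wild type Col-0 and the mutant rpt2a-2 with mock or Pma treatment and with a local or a systemic experiment. Pma is the leaf pathogen Pseudomonas syringae pv. maculicola, with the strain spelled ES4362 in the labels. Per the labels, lower leaves of plants 5 weeks old were infiltrated with Pma at an OD600 of 0.005 in 10 mM MgCl2, or with 10 mM MgCl2 alone as mock. In the systemic experiment upper leaves were also infiltrated 38 h after the first infiltration, and material was taken 48 h after the first infiltration. The labels do not state what the second infiltration contained, nor whether it was the same for mock and Pma plants. They do not state which leaves were harvested either, so systemic leaves stands here for the leaves sampled in the systemic experiment, whichever they were. RNA was extracted with NucleoZOL, per the labels' protocols.

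The authors deposited a single table of raw read counts per annotated gene, with 1 column per library. Per the submitters' processing notes the counts came from FastQC, STAR and HTSeq on the genome build TAIR10, and the notes give no versions or settings. Strand use, read layout and the annotation release were not stated, so reads from overlapping or antisense genes could not be told apart. The values were checked to be whole numbers with totals that differed between libraries. All columns were matched to samples by the library names in the labels, and 0 columns remained without a sample. Gene names came from a gene table of the assembly TAIR10.1, in which 32548 of the 32833 gene identifiers of the count table were found. No coordinates were used, since the 2 builds carry different names.

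The total per library ranged from 16.8 to 38.2 M counts. A gene with 0 counts in a group was given a floor of 3 counts over the 3 libraries of that group, and its fold change is written as at least the ratio to that floor. Where a group held 1 to 3 counts, the ratio is given with its 95% counting interval. These floors and intervals cover counting error only. Members of gene families with near-identical copies, such as RPT2A and RPT2B, the GSTF6 and GSTF7 pair or CYP71A12 and its neighbour copy, may share reads, so their separate levels are uncertain.

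Each experiment was fitted on its own with edgeR 4.0.16 in R 4.3.3, with 12 libraries in 4 groups that shared an estimate of the spread. Genes were kept by filterByExpr, which left 19345 genes in the local and 18723 in the systemic experiment. Libraries were scaled by TMM, and the robust quasi-likelihood F test was applied to each comparison. Every adjusted p of a gene comes from this edgeR test with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Within each experiment 5 comparisons were tested: Pma against mock in each genotype, the difference between these responses, and rpt2a-2 against Col-0 under mock and under Pma. The difference between the local and the systemic response of Col-0 was tested in a fit of all 24 libraries with 19776 genes, each Pma group being set against the mock group of its own experiment. The labels give the experiment as a batch, so levels were not compared directly between the experiments. Values in CPM (counts scaled to a library total of 1e6) are TMM-scaled means with the standard deviation of 3 libraries (n = 3), and log2 fold changes carry standard errors (SE).

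The 25 gene lists held 413 members in all. They covered salicylic acid synthesis and signalling, systemic acquired resistance and N-hydroxypipecolic acid, pathogenesis-related and salicylic acid marker proteins, cysteine-rich receptor-like kinases, pattern-triggered immunity, tryptophan and camalexin synthesis, indole glucosinolates, aliphatic glucosinolates, jasmonate synthesis and signalling, ethylene synthesis and response, abscisic acid response, photosynthesis, proteasome, autophagy, cytosolic heat shock response, endoplasmic reticulum protein folding, leaf senescence, flavonoids and anthocyanins, cell wall loosening, DNA replication and cell division, circadian clock, and markers of guard cells, phloem, xylem and epidermis. RPT2A was left out of the proteasome list, which holds the transcription factors NAC53 and NAC78 and the activator PA200 besides the subunits. Lists were tested with limma's camera (3.58.1) on voom values with a preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over the lists of a comparison. With an estimated correlation 1 of 126 calls passed, that of the proteasome list in local mock plants. Where a list is described, the number of its genes adjusted over the list alone is given beside that over all genes tested.

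Named genes followed a rule. In each comparison RPT2A, RPT2B, PR1, ICS1, FMO1 and ALD1 were always named. The 5 genes with the largest rise and the 5 with the largest fall were added among called genes with a mean of at least 5 CPM in a compared group and, for 2 groups, no overlap between libraries. The called member of each list with the smallest adjusted p was added, or the 3 such members where the list passed its test. The text describes a part of the genes that the rule gave, chosen after their values were seen. All 172 called genes it names in 2-group comparisons had no overlap between the groups' 3 libraries. Calls favour this and the rule demanded it of the largest changes, so chance (10% of genes) is no benchmark.

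The groups, comparisons, tests, gene lists, rule for named genes and most alternatives were chosen before the data were examined. The alternatives were RLE size factors, no filter, a filter of at least 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, the sample number as a replicate block, fits of all 24 or of only 6 libraries, and leaving out each library in turn. Scaling by library size alone, and list tests without 1 library of the systemic experiment, were added after the data had been seen.

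The steps were tested on simulated counts with 200 changed genes, so rates need not hold where far more were called, as after local Pma. For local Pma in Col-0 edgeR recovered 87% of 2-fold and 97% of 4-fold changes, with 2.13% false calls. For systemic Pma in Col-0 it recovered 63% and 99%, with 2.99% false calls. For the genotype difference in response it recovered 62% and 94% (local) and 23% and 92% (systemic), with 5.45% and 4.17% false calls. The list test called 8 of 8 changed (right direction) and 0 unchanged lists. Unlike most real calls, all 8 passed with an estimated correlation, so real lists were not covered. DESeq2 made 15.2% (local) and 20.7% (systemic) false calls for Col-0. Figures used matplotlib 3.10.9 in Python 3.11.15.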

Results

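RNA sequencing gave read counts for 32833 genes in 24 leaf libraries, of which 25759 genes had a count in some library. The 8 groups of 3 libraries were Col-0 and rpt2a-2, each after mock or Pma treatment, in a local and in a systemic experiment. Mean totals per group were 26.2 to 32.4 M counts. Single libraries held 16.8 M (Col-0 systemic mock replicate 1) to 38.2 M counts (rpt2a-2 systemic mock replicate 3) with 20738 to 21866 genes detected. Values after ± are standard deviations (SD, n = 3). The 10 most abundant genes took 11.1% of counts in Col-0 local mock and 5.77% in Col-0 local Pma, and 11% and 5.87% in rpt2a-2. A principal component held 86.4% of the variance of the local libraries, while the leading component of the systemic libraries held 51% and set rpt2a-2 systemic Pma replicate 1 (score 72.3) apart from replicates 2 and 3 (scores -5 and -10.9). Col-0 systemic Pma libraries had scores of 57.8, 74.9 and 33.6 on it, and the 6 systemic mock libraries scores of -72.2 to -11.7, so that replicate 1 lay with the wild-type Pma libraries on it. On the next component (16.5%) it did not, with the lowest score of the 12 (-63.1) against 8.5, 16.5 and 27.6 for those libraries. Replicate 3 of rpt2a-2 systemic mock (-34.9) lay apart from its replicates 1 and 2 (-70.8 and -72.2).

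RPT2A (AT4G29040) encodes an ATPase subunit of the 19S regulatory particle of the proteasome, and its transcript was lower in rpt2a-2 in every condition. In local mock leaves it reached 121 ± 8.57 CPM in Col-0 and 28.9 ± 3.36 CPM in rpt2a-2 (edgeR log2 fold change -2.06, SE 0.11, adjusted p = 7.38e-07). After local Pma the levels were 263 ± 23.3 and 93.8 ± 4.95 CPM (log2 -1.49, adjusted p = 2.01e-06). Systemic mock leaves held 97.5 ± 6.69 and 21.6 ± 1.53 CPM (log2 -2.17, adjusted p = 0.0061), and systemic Pma leaves 127 ± 17.1 and 27.9 ± 12.5 CPM (log2 -2.19, adjusted p = 0.00293). The paralog RPT2B (AT2G20140) was higher in rpt2a-2 in local mock leaves (log2 0.61, SE 0.10, adjusted p = 0.00503) and local Pma leaves (log2 1.70, SE 0.10, adjusted p = 2.18e-07). In systemic leaves its differences of 0.32 (adjusted p = 0.214) and 0.42 (adjusted p = 0.146) did not pass. Reads may be shared between both copies, and where rpt2a-2 carries its lesion is not given in the labels, so part of the remaining RPT2A signal may come from outside it.

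**Figure D1:**
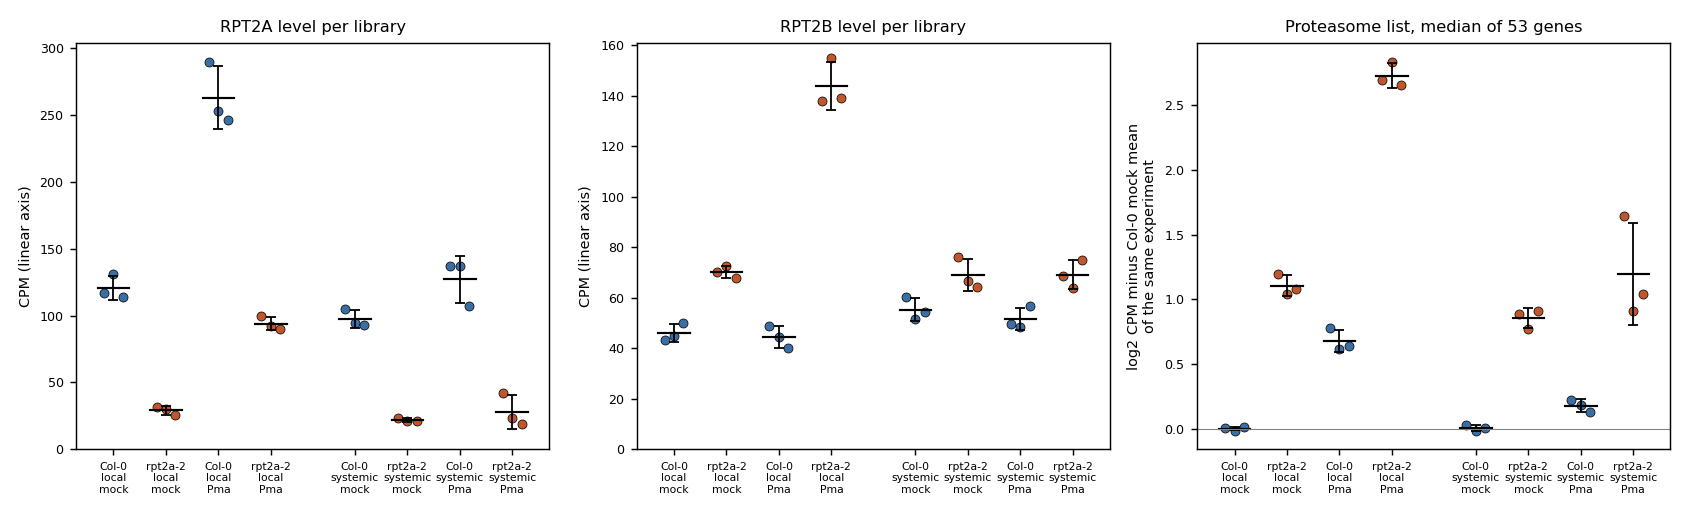
CPM of RPT2A and of RPT2B per library on linear axes, and the median log2 level of 53 proteasome genes relative to the mean of Col-0 mock of the same experiment, in the 8 groups of 3 libraries, with points for libraries and bars for mean ± SD. RPT2A lay lower in rpt2a-2 in each condition, from 121 against 28.9 CPM in local mock leaves to 127 against 27.9 CPM in systemic Pma leaves.

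Local Pma against mock in Col-0 asked how wild-type leaves respond to direct infection. Salicylic acid and immune genes rose together while photosynthesis genes fell. PR1 (AT2G14610), a marker of salicylic acid responses, rose from 9.98 ± 8.98 to 11100 ± 1970 CPM (log2 10.12, SE 1.00, adjusted p = 2.02e-06). ICS1 (AT1G74710), the isochorismate synthase of salicylic acid synthesis, rose 5.70-fold to 151 ± 43.3 CPM. FMO1 (AT1G19250) and ALD1 (AT2G13810), enzymes of N-hydroxypipecolic acid synthesis, rose from 0.219 ± 0.297 to 381 ± 79.9 CPM and from 0.483 ± 0.514 to 219 ± 25.8 CPM (adjusted p = 1.94e-08 and 6.74e-08).

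In the salicylic acid list 21 of 22 genes rose (21 adjusted over the list alone, median log2 2.48, camera adjusted p = 2.65e-07), among them PBS3 (AT5G13320), which acts in salicylic acid synthesis (log2 6.13), and the salicylic acid receptor gene NPR3 (AT5G45110, log2 2.45). All 11 pathogenesis-related genes rose (11 adjusted over the list alone, median 4.04, adjusted p = 2.83e-05), including SAG13 (AT2G29350, 2680 ± 173 CPM) and the chitinase PR3 (AT3G12500, log2 6.12). In pattern-triggered immunity 19 of 22 genes rose and 1 fell (the same numbers adjusted over the list alone, median 1.83, adjusted p = 3.34e-06), and its member NHL10 (AT2G35980) rose 937-fold. Of 12 tryptophan and camalexin genes 11 rose (11 adjusted over the list alone, median 2.85, adjusted p = 1.09e-05), among them the anthranilate synthase ASA1 (AT5G05730, log2 3.57) and CYP79B2 (AT4G39950, log2 4.53). In the jasmonate list 23 of 28 genes rose and 2 fell (the same over the list alone, median 2.47, adjusted p = 1.38e-05), with the repressor genes JAZ1 (AT1G19180) at log2 4.36 and JAZ8 (AT1G30135) at log2 6.76. The calls of these 5 lists were lost with an estimated correlation (adjusted p = 0.317 with an estimated correlation for each).

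All 47 photosynthesis genes fell (47 adjusted over the list alone, median -3.42, adjusted p = 7.94e-17), such as RBCS2B (AT5G38420), a small subunit of Rubisco, from 3830 ± 947 to 140 ± 8.39 CPM, and PSAG (AT1G55670) of photosystem I (log2 -3.59). All 12 senescence genes (median 3.60, adjusted p = 3.79e-05), among them the transcription factor gene ORE1 (AT5G39610, log2 7.71) and the chlorophyll breakdown gene SGR1 (AT4G22920, log2 2.43), and all 13 genes of endoplasmic reticulum protein folding (median 2.44, adjusted p = 1.54e-06), with ERDJ3B (AT3G62600) at log2 2.44, rose. In autophagy 14 of 16 genes rose (median 1.29, adjusted p = 2.83e-05), such as ATG8A (AT4G21980, log2 2.61), and numbers adjusted over the list alone were the same for these 4 lists. Each of the 4 lists had adjusted p = 0.317 with an estimated correlation. In the proteasome list 48 of 53 genes rose (48 adjusted over the list alone, median 0.64, adjusted p = 5.85e-10), including the transcription factor NAC53 (AT3G10500, log2 3.07) and the activator PA200 (AT3G13330, log2 2.14). All 7 epidermis markers fell (7 adjusted over the list alone, median -5.12, adjusted p = 0.00328), among them LTP1 (AT2G38540), a lipid transfer protein gene (963 ± 290 to 3.68 ± 1.98 CPM), and the cuticle gene FDH (AT2G26250, log2 -4.93). Proteasome and epidermis lists had adjusted p = 0.335 with an estimated correlation.

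Of the heat shock list 13 of 14 genes rose (median 4.61, adjusted p = 0.00169), with HSFB1 (AT4G36990) at log2 5.42 and HSP17.6B (AT2G29500) at log2 4.55. Cysteine-rich receptor-like kinases rose for 10 of 13 genes and fell for 2 (median 1.91, adjusted p = 0.012), with CRK36 (AT4G04490) at log2 4.52, and indole glucosinolate genes rose for 6 of 9 and fell for 1 (median 1.16, adjusted p = 0.0391). In DNA replication 13 of 14 genes fell (median -2.63, adjusted p = 0.00497), such as the ribonucleotide reductase gene TSO2 (AT3G27060, log2 -3.23). These 4 lists had adjusted p = 0.419 with an estimated correlation. In the list of systemic acquired resistance 8 of 10 genes rose and 1 fell (median 2.90, adjusted p = 0.0177, adjusted p = 0.346 with an estimated correlation). Cell wall loosening genes fell for 9 of 11 and rose for 1 (median -3.73, adjusted p = 0.0238, adjusted p = 0.373 with an estimated correlation), with the expansin EXPA3 (AT2G37640) at log2 -8.50. Aliphatic glucosinolate genes fell for 11 of 15 (median -1.92, adjusted p = 0.012, adjusted p = 0.542 with an estimated correlation), among them the regulator MYB29 (AT5G07690, log2 -5.05) and UGT74C1 (AT2G31790, log2 -2.23). For these 7 lists the numbers adjusted over the list alone were the same. With scaling by library size alone, the list of systemic acquired resistance (adjusted p = 0.0622) and the indole glucosinolate list (adjusted p = 0.096, and 0.052 with RLE) no longer passed.

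The lists of ethylene (5 higher and 1 lower of 11, median 0.74, adjusted p = 0.118), abscisic acid (5 and 4 of 14, median -0.39, mean -0.36 against a test direction of up, adjusted p = 0.796), flavonoids (3 and 6 of 13, median -0.99, adjusted p = 0.577) did not pass. The clock list (5 and 1 of 12, 4 and 1 adjusted over the list alone, median 0.29, adjusted p = 0.215) did not either. The marker lists of guard cells (1 higher and 5 lower of 7, median -1.08, adjusted p = 0.336), phloem (2 and 2 of 9, median -0.18, adjusted p = 0.993) and xylem (0 and 6 of 6, median -2.22, adjusted p = 0.0936) did not pass either. The guard cell potassium channel gene KAT1 (AT5G46240) rose 5.11-fold.

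Among the largest rises were those of GSTU3 (AT2G29470), a glutathione transferase gene with 1 count in Col-0 local mock (ratio 22300, 95% counting interval 4010 to 882000), the dioxygenase DOX1 (AT3G01420, 923 ± 92.6 CPM), the trypsin inhibitor KTI1 (AT1G73260, 1320 ± 175 CPM) and OSM34 (AT4G11650, 696 ± 321 CPM). BSMT1 (AT3G11480), a methyltransferase gene for methyl salicylate with 0 counts in mock, was at least 1620-fold higher. GER3 (AT5G20630), a germin gene with 3 counts after Pma, was lower by a ratio of 908 (counting interval 310 to 4410), and AT2G10940, of the lipid transfer protein superfamily, fell from 963 ± 486 to 1.31 ± 1.14 CPM. RPT2A rose 2.18-fold (adjusted p = 1.15e-06), while RPT2B was at log2 -0.05 (adjusted p = 0.634), a sign that turned with RLE scaling (0.05). In all, edgeR called 15020 of 19345 genes (77.6%), 6915 higher and 8105 lower, of which 9196 changed at least 2-fold. The share of higher genes was 46% and became 57.9% with scaling by library size alone. The median change of all tested genes was -0.12 with TMM, -0.01 with RLE and 0.22 with library size alone.

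In rpt2a-2 local Pma against mock addressed the same question in the mutant. PR1 rose from 10.3 ± 8.16 to 8280 ± 2700 CPM (log2 9.66, SE 0.98, adjusted p = 2.48e-06), ICS1 3.25-fold, FMO1 from 0.164 ± 0.184 to 265 ± 73.6 CPM and ALD1 from 0.26 ± 0.217 to 130 ± 67.3 CPM. All 53 proteasome genes rose (53 adjusted over the list alone, median log2 1.63, camera adjusted p = 2.01e-17), with the subunit genes RPT6B (AT5G20000, 688 ± 43.2 CPM, log2 2.18), RPT5B (AT1G09100, log2 2.16) and PBE2 (AT3G26340, log2 1.93). RPT2A rose 3.24-fold and RPT2B 2.05-fold.

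Of 15 aliphatic glucosinolate genes 14 fell (14 adjusted over the list alone, median -3.75, adjusted p = 8.99e-05, adjusted p = 0.386 with an estimated correlation). Among them were MYB28 (AT5G61420), a regulator of this pathway, from 76.6 ± 12.8 to 4.36 ± 0.446 CPM, the cytochrome P450 gene CYP83A1 (AT4G13770, log2 -4.25) and the glucosyltransferase gene UGT74C1 (log2 -3.58). As in Col-0, salicylic acid genes rose for 21 of 22 (median 2.23, adjusted p = 6.02e-06, adjusted p = 0.348 with an estimated correlation), with PBS3 at 510 ± 111 CPM. Pathogenesis-related genes rose for 11 of 11 (median 4.88, adjusted p = 4.58e-05), with SAG13 at 3820 ± 178 CPM. Jasmonate genes rose for 24 of 28 with 2 lower (median 2.54, adjusted p = 6.02e-06), with JAZ1 at log2 4.51. Folding genes rose for 13 of 13 (median 2.34, adjusted p = 8.16e-06), with ERDJ3B at log2 2.3. All 47 photosynthesis genes fell (median -3.42, adjusted p = 6.02e-18), with RBCS2B at log2 -4.82. The proteasome list and these last 4 lists had adjusted p = 0.337 with an estimated correlation. Other lists that passed were pattern-triggered immunity (19 higher and 1 lower of 22, median 1.44), tryptophan and camalexin (11 and 1 of 12, 2.73), autophagy (15 and 0 of 16, 1.5), heat shock (14 and 0 of 14, 4.46) and senescence (12 and 0 of 12, 3.75). Lists of cell wall loosening (1 and 8 of 11, median -4.3), DNA replication (0 and 13 of 14, -2.23), xylem (0 and 6 of 6, -2.48) and epidermis markers (0 and 7 of 7, -4.65) were lower. These 9 lists had adjusted p of 9.37e-06 to 0.0411, and of 0.337 to 0.435 with an estimated correlation. Systemic acquired resistance (adjusted p = 0.0546), cysteine-rich receptor-like kinases (0.0958) and indole glucosinolates (0.0778) did not pass. Numbers adjusted over the list alone were the same in all of these.

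BSMT1 was at least 6080-fold higher after Pma. TPS10 (AT2G24210), a terpene synthase gene, had 3 counts in mock (ratio 11700, counting interval 4000 to 56700) and MSRB7 (AT4G21830), a methionine sulfoxide reductase gene, had 1 (ratio 9430, 1690 to 372000), while DOX1 rose to 720 ± 140 CPM. GER3 had 1 count after Pma (ratio 2570 lower, 462 to 102000), and SAUR68 (AT1G29510) was at least 174-fold lower. edgeR called 15067 of 19345 genes (77.9%), 7387 higher and 7680 lower. Both genotypes shared 6201 higher genes (2640 expected by chance) and 6903 lower genes (3220 expected), 148 moved in opposite directions, and log2 fold changes had a Pearson r of 0.94 across genes, which are not independent replicates.

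The difference between these 2 local responses was tested directly. Proteasome genes rose more in rpt2a-2 and aliphatic glucosinolate genes fell more. Of 53 proteasome genes 45 had a higher response (47 adjusted over the list alone, median log2 0.86, camera adjusted p = 5.9e-36, adjusted p = 0.299 with an estimated correlation). The subunit gene PBB1 (AT3G27430) rose from 103 ± 7.91 to 432 ± 37.8 CPM in rpt2a-2 and from 66.1 ± 2.25 to 89.4 ± 3.08 CPM in Col-0 (log2 difference 1.63, SE 0.14, adjusted p = 9.8e-05), with PBE2 at 1.41 and PBC2 (AT1G77440) at 1.35. RPT2B, unchanged by the test in Col-0, differed by 1.09 (SE 0.14, adjusted p = 0.00132) and RPT2A by 0.57 (adjusted p = 0.0389). Of 15 aliphatic glucosinolate genes 8 fell more in rpt2a-2 (11 adjusted over the list alone, median -1.69, adjusted p = 8.84e-10, adjusted p = 0.917 with an estimated correlation), among them MYB28 (-2.06, SE 0.32, adjusted p = 0.00372), CYP83A1 (-1.90) and UGT74C1 (-1.35).

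In the abscisic acid list 2 of 14 genes rose more in rpt2a-2 (7 adjusted over the list alone, median 1.00, adjusted p = 0.00869), the phosphatase genes ABI1 (AT4G26080, 0.78) and ABI2 (AT5G57050, 1.03). Of 22 pattern-triggered immunity genes 1 had a lower response (1 adjusted over the list alone, median -0.37, adjusted p = 0.00882), the NADPH oxidase gene RBOHF (AT1G64060, -0.81). Both lists had adjusted p = 0.917 with an estimated correlation. VSP2 (AT5G24770), a vegetative storage protein gene of the jasmonate response, rose from 5.49 ± 2 to 90.4 ± 16.5 CPM in rpt2a-2 against 8.67 ± 3.94 to 21.4 ± 12 CPM in Col-0 (2.72, adjusted p = 0.0293). Stronger responses in rpt2a-2 were also called for EPS1 (AT5G67160) of salicylic acid synthesis (1.01), NYC1 (AT4G13250) of chlorophyll breakdown (1.41) and the autophagy receptor NBR1 (AT4G24690, 0.66). The photoperiod gene FKF1 (AT1G68050) had a difference of 0.95, and CRK10 (AT4G23180) of -0.78. AT1G15180, a MATE efflux family gene, fell in Col-0 from 39.4 ± 7.65 to 4.25 ± 0.483 CPM but stood at 50.9 ± 1.81 and 71.7 ± 4.46 CPM in rpt2a-2 (3.71, adjusted p = 3.88e-06). The hydroxyproline-rich glycoprotein gene AT1G10790 differed by 4.03, and the cellulose synthase-like gene CSLD5 (AT1G02730) by -3.85. PR1 (-0.46), ICS1 (-0.81), FMO1 (-0.19) and ALD1 (0.09) did not pass (adjusted p = 0.81, 0.121, 0.949 and 0.968).

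For this difference edgeR called 1637 of 19345 genes, 1031 higher and 606 lower in rpt2a-2. The share of higher genes, 63%, fell to 45.7% with RLE and 26.8% with library size alone, so the balance of directions depended on scaling. Without single libraries the count fell to as few as 876 (Col-0 local Pma replicate 3). Of the named calls 11 of 22 held without each library in turn. RPT2A (adjusted p = 0.0626), ABI2 (0.0555) and NBR1 (0.0637) did not pass with RLE.

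rpt2a-2 against Col-0 in local mock leaves asked how the mutant differs before infection. Proteasome genes were higher in rpt2a-2 for 46 of 53 members (48 adjusted over the list alone, median log2 1.14, camera adjusted p = 3.17e-88), and this list alone also passed with adjusted p = 0.0233 with an estimated correlation. RPT6B stood at 152 ± 8.39 against 31.9 ± 2.3 CPM (log2 2.25, SE 0.10, adjusted p = 2.57e-07), with RPT5B at 2.11 and PBB2 (AT5G40580) at 2.07. NAC103 (AT5G64060), a NAC transcription factor gene, was higher at 13.5 ± 2.44 against 0.208 ± 0.106 CPM (log2 6.02). PR1 (log2 0.05), ICS1 (-0.10), FMO1 (-0.34) and ALD1 (-0.85) did not pass (adjusted p = 0.988, 0.861, 0.916 and 0.693).

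Further lists that passed were lower salicylic acid genes (0 of 22 called, 0 adjusted over the list alone, median -0.19, adjusted p = 0.00847) and lower cysteine-rich receptor-like kinases (2 of 13 lower, 2 adjusted over the list alone, median -0.37, adjusted p = 0.00847), with CRK10 at -0.78. Photosynthesis genes were lower too (0 of 47 and 0, median -0.22, adjusted p = 0.00584). Higher lists were flavonoids (1 of 13, 5 adjusted over the list alone, median 0.45, adjusted p = 0.00894), with the anthocyanin regulator PAP1 (AT1G56650) at 0.84, and jasmonate (2 of 28 and 2, median 0.22, adjusted p = 0.0202), with CYP94B3 (AT3G48520), which oxidises jasmonoyl-isoleucine, at 4.50 and NAC019 (AT1G52890) at 2.3. Xylem markers were also higher (0 of 6 and 1, median 0.74, adjusted p = 0.00847). All 6 had adjusted p = 0.955 with an estimated correlation, and with library size alone flavonoids (adjusted p = 0.053) and jasmonate (0.0648) no longer passed. Single genes were FKF1, lower by log2 -0.89, and TSO2, higher by 0.77. NEET (AT5G51720), a gene for a 2Fe-2S binding protein, was at 2.9 ± 1.35 against 31 ± 14.9 CPM (log2 -3.41). Called in all were 533 of 19345 genes, 321 higher and 212 lower (60.2% higher, or 72.8% with library size alone). The count fell to as few as 265 (without Col-0 local mock replicate 1), and 11 of 17 named calls held without each library in turn.

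rpt2a-2 against Col-0 after local Pma compared the infected leaves. Proteasome genes were higher for 49 of 53 members (50 adjusted over the list alone, median log2 2.03, camera adjusted p = 2.31e-47, adjusted p = 0.147 with an estimated correlation). Examples were PBE2 at 173 ± 12.6 against 19.9 ± 0.825 CPM (log2 3.12, SE 0.09, adjusted p = 2.64e-09), RPT6B (2.79) and RPN5B (AT5G64760, 2.02). ICS1 was lower in rpt2a-2 at 79.9 ± 21.4 against 151 ± 43.3 CPM (log2 -0.91, SE 0.21, adjusted p = 0.00717), whereas PR1 (-0.42), FMO1 (-0.53) and ALD1 (-0.76) did not pass (adjusted p = 0.662, 0.261 and 0.137). Aliphatic glucosinolate genes were lower for 14 of 15 (15 adjusted over the list alone, median -1.83, adjusted p = 5.94e-08, adjusted p = 0.729 with an estimated correlation), with MYB28 (-2.28), CYP83A1 (-1.78) and UGT74C1 (-1.46). NAC103 stood at 39.8 ± 1.71 against 0.153 ± 0.0404 CPM (log2 7.97).

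In 3 immune lists more genes were lower than higher in rpt2a-2, and each had adjusted p = 0.729 with an estimated correlation. In the salicylic acid list 10 of 22 genes were lower and 2 higher (12 and 2 adjusted over the list alone, median -0.60, adjusted p = 0.00166), among them the receptor genes NPR1 (AT1G64280, -0.62) and NPR4 (AT4G19660, -0.57), while EPS1 was higher (1.23). Cysteine-rich receptor-like kinases were lower for 7 of 13 (7 adjusted over the list alone, median -0.73, adjusted p = 0.00171), with CRK10 (-1.55) and CRK14 (AT4G23220, -1.57). Pattern-triggered immunity genes were lower for 6 of 22 (6, median -0.20, adjusted p = 0.00538), with WRKY53 (AT4G23810, -1.29) and the kinase gene MPK3 (AT3G45640, -0.79). Jasmonate genes were higher for 13 of 28 and lower for 1 (14 and 1 adjusted over the list alone, median 0.47, adjusted p = 0.00377), with CYP94B3 (3.53), BSMT1 (2.03) and the allene oxide cyclase AOC1 (AT3G25760, 1.24). Abscisic acid genes were higher for 7 of 14 (8, median 0.67, adjusted p = 0.0175), with ABI1 (0.66) and ABI2 (0.79), and flavonoid genes for 6 of 13 (6, median 1.22, adjusted p = 0.0324), with PAP1 (1.11) and the transferase TT19 (AT5G17220, 3.41). Photosynthesis genes were lower for 9 of 47 (6 adjusted over the list alone, median -0.30, adjusted p = 0.00105), with Rubisco activase RCA (AT2G39730) at -0.76, and guard cell markers for 4 of 7 (5, median -0.61, adjusted p = 0.0263), with MYB60 (AT1G08810, -1.29) and KAT1 (-0.60). The 5 other lists of this paragraph had adjusted p = 0.729 with an estimated correlation.

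Outside the lists that passed, AZI1 (AT4G12470) of systemic resistance was higher (2.82), as was NBR1 (1.1), while WAK2 (AT1G21270, -0.87) and LUP5 (AT1G66960), a terpenoid cyclase gene (-3.89), were lower. edgeR called 6751 of 19345 genes, 3723 higher and 3028 lower. The share of higher genes was 55.1%, but 41.7% with RLE and 39.7% with library size alone. ABI2 lost its call without Col-0 local Pma replicate 3 (0.61, adjusted p = 0.0673) and KAT1 without rpt2a-2 local Pma replicate 3 (-0.49, adjusted p = 0.0738).

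Systemic Pma against mock in Col-0 concerned systemic acquired resistance, in which infection of lower leaves prepares upper leaves. Genes of protein folding in the endoplasmic reticulum rose. Of 13 folding genes 12 rose (13 adjusted over the list alone, median log2 1.63, camera adjusted p = 1.32e-17). They included HSP90.7 (AT4G24190) from 355 ± 43.1 to 1240 ± 189 CPM (edgeR log2 1.81, SE 0.24, adjusted p = 0.0094), the calnexin gene CNX1 (AT5G61790, 1.56), the calreticulin gene CRT1A (AT1G56340, 1.23) and the chaperone gene BIP3 (AT1G09080, 4.74). Of 11 pathogenesis-related genes 4 rose (9 adjusted over the list alone, median 3.27, adjusted p = 1.49e-07), such as PR2 (AT3G57260) from 23.7 ± 4.37 to 563 ± 217 CPM (log2 4.57, SE 0.77, adjusted p = 0.0185) and PR5 (AT1G75040, 3.27). PR1 stood at 202 ± 103 against 5.44 ± 4.6 CPM and did not pass (log2 5.25, SE 1.34, adjusted p = 0.0641).

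Tryptophan and camalexin genes rose for 5 of 12 (10 adjusted over the list alone, median 0.70, adjusted p = 1.49e-07), with CYP71A12 (AT2G30750, 2.93), IGPS (AT2G04400, 0.76) and TSB2 (AT4G27070, 0.84). This list, the folding list and the pathogenesis-related list had adjusted p = 0.241 with an estimated correlation. In the list of systemic acquired resistance 2 of 10 genes rose (4 adjusted over the list alone, median 2.47, adjusted p = 0.000758), FMO1 (0.0863 ± 0.0482 to 2.61 ± 2.07 CPM, adjusted p = 0.0445) and the protease gene AED1 (AT5G10760, 3.50). Of the indole glucosinolate genes 1 of 8 rose (4, median 1.04, adjusted p = 0.00235), the cytochrome P450 gene CYP83B1 (AT4G31500, 0.88). Both lists had adjusted p = 0.289 with an estimated correlation. Cysteine-rich receptor-like kinases rose for 4 of 13 (6 higher and 1 lower adjusted over the list alone, median 1.79, adjusted p = 3.97e-05, adjusted p = 0.319 with an estimated correlation), with CRK6 (AT4G23140, 3.54) and CRK7 (AT4G23150, 3.79). In the salicylic acid list 1 of 22 genes rose (8 adjusted over the list alone, median 0.96, adjusted p = 2.29e-05, adjusted p = 0.512 with an estimated correlation), the hydroxylase gene DLO1 (AT4G10500, 4.67). ICS1 was at 1.67 (adjusted p = 0.127) and ALD1 at 6.40 (adjusted p = 0.0613). Pattern-triggered immunity genes rose for 2 of 20 (3 higher and 1 lower adjusted over the list alone, median 0.25, adjusted p = 0.0121, adjusted p = 0.576 with an estimated correlation), WRKY53 (2.48) and the kinase gene FRK1 (AT2G19190, 3.49).

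Smaller list shifts passed as well. Photosynthesis (median -0.24, adjusted p = 6.47e-07) and DNA replication (median -0.53, adjusted p = 0.000762) were lower and autophagy higher (median 0.32, adjusted p = 0.000462), each with 0 genes called, 0 adjusted over the list alone and adjusted p = 0.52 with an estimated correlation. Proteasome genes were higher (median 0.18, adjusted p = 5.83e-05) and aliphatic glucosinolates (median -0.28, adjusted p = 0.0171) and flavonoids (median -0.61, adjusted p = 0.0333) lower, with 0 genes called, 0 adjusted over the list alone and adjusted p = 0.576 with an estimated correlation. Markers of guard cells (1 of 7 lower, 4 adjusted over the list alone, median -0.44, adjusted p = 0.000291), with MYB60 at -0.63, and of the epidermis (0 and 5 of 7, median -0.54, adjusted p = 0.000254) were lower. Both had adjusted p = 0.241 with an estimated correlation.

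Single rises were those of AIG1 (AT1G33960), a nucleoside triphosphatase family gene (5.20), LUP5 (4.74), PCR1 (AT1G14880, 4.66) and the phloem sucrose transporter SWEET11 (AT3G48740, 0.77), and the falls of KCS19 (AT5G04530) of fatty acid elongation (-2.26), ATGA2OX1 (AT1G78440) of gibberellin breakdown (-2.17) and ICS2 (AT1G18870), the other isochorismate synthase gene (-1.97). RPT2A was at 0.38 and RPT2B at -0.10 (adjusted p = 0.378 and 0.636). edgeR called 482 of 18723 genes, 285 higher and 197 lower (59.1% higher, or 70% with library size alone), and 257 of the higher genes also rose after local Pma (95.6 expected). The count was 2647 with only 6 libraries. It was 53, 18 and 12 without Col-0 systemic mock replicate 1, 2 or 3. It was 38, 42 and 849 without Col-0 Pma replicate 1, 2 or 3. Of the 25 named calls 4, 1, 0, 5, 4 and 24 were left in that order.

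**Figure D2:**
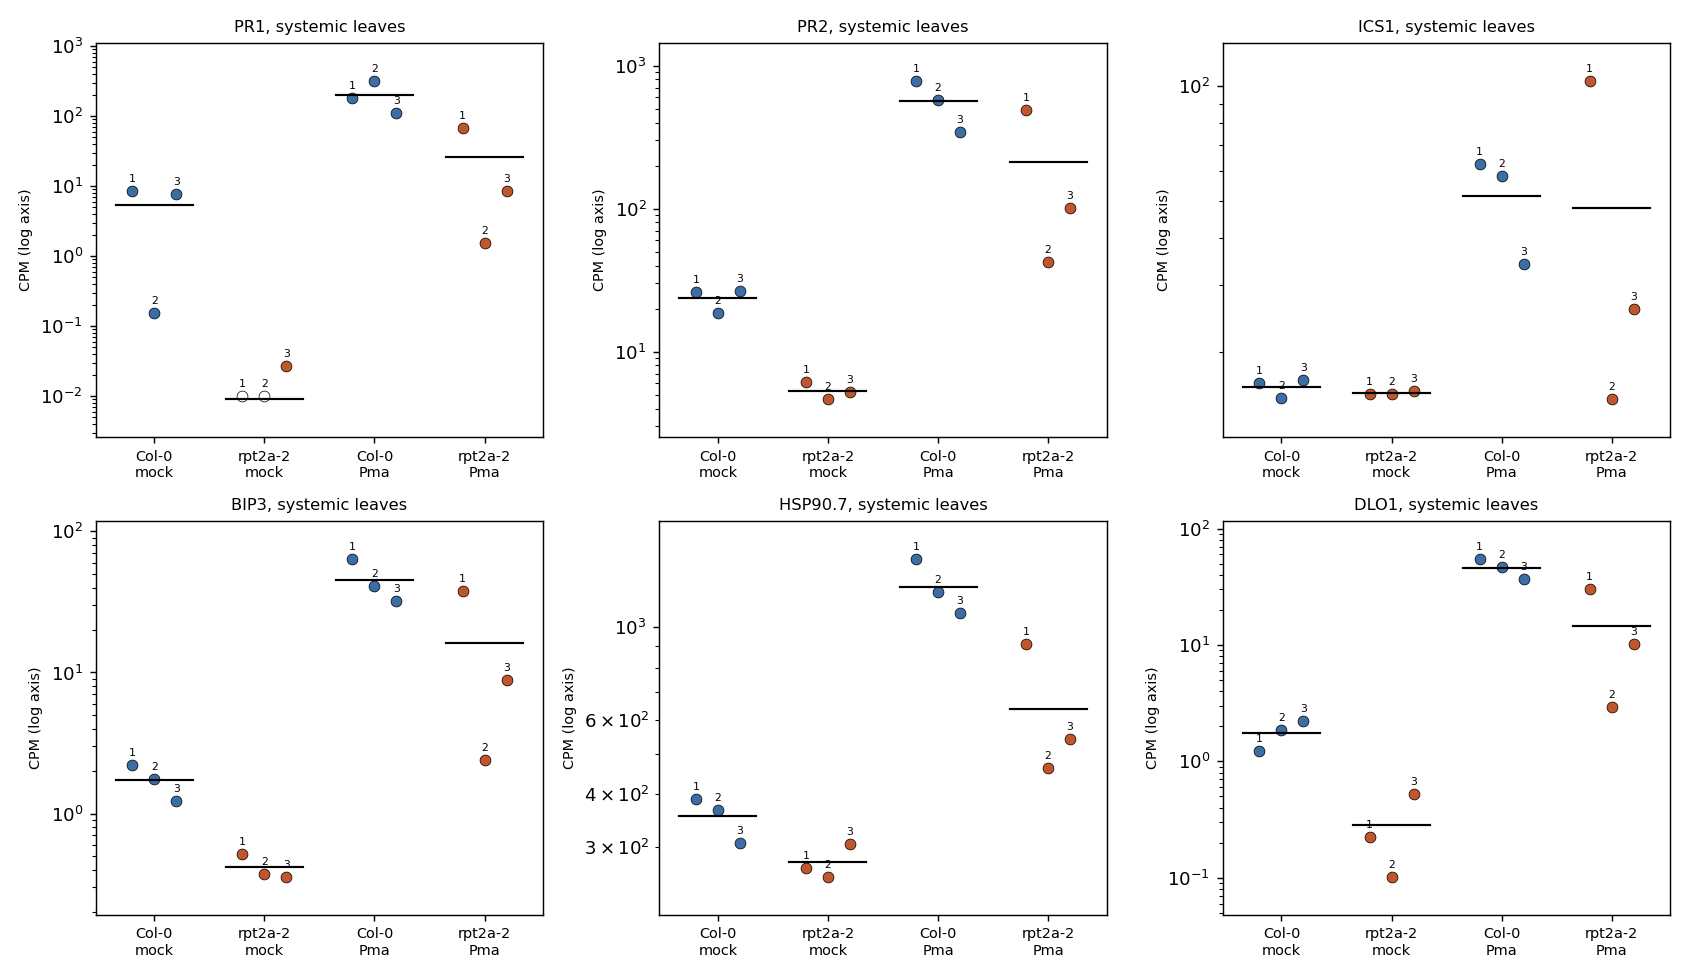
CPM on a log axis of PR1, PR2, ICS1, BIP3, HSP90.7 and DLO1 in the 12 systemic libraries, with digits for the replicate number, a line for the group mean and open circles at 0.01 for libraries with 0 counts. PR2 averaged 563 CPM in Col-0 Pma and 210 CPM in rpt2a-2 Pma, where replicate 1 held 487 CPM against 42.4 and 101 CPM in replicates 2 and 3.

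Systemic Pma against mock in rpt2a-2 gave rises of folding genes and of some defence genes too. Of 13 folding genes 11 rose (13 adjusted over the list alone, median log2 1.39, camera adjusted p = 1.07e-13), such as CNX1 (176 ± 30.2 to 410 ± 95.2 CPM, log2 1.22, SE 0.20, adjusted p = 0.031), CRT1A (1.03) and SDF2 (AT2G25110, 1.21). Pathogenesis-related genes rose for 4 of 11 (10 adjusted over the list alone, median 3.12, adjusted p = 2.97e-07), with PR2 (5.34 ± 0.723 to 210 ± 241 CPM) and PR5 (3.04), and cysteine-rich receptor-like kinases for 5 of 13 (10, median 2.84, adjusted p = 3.31e-07), with CRK6 (4.0). These 3 lists had adjusted p = 0.448 with an estimated correlation. The medians of the last 2 were 2.39 and 1.94 without rpt2a-2 systemic Pma replicate 1. PR1 stood at 25.8 ± 36 CPM against 1 count in the mock libraries (ratio 2790, counting interval 501 to 110000) and did not pass (adjusted p = 0.0525). Its 3 Pma libraries were at 67.2, 1.56 and 8.62 CPM, so the ratio rested on replicate 1. It passed without replicate 2 or 3 of that group (adjusted p = 0.0227 and 0.0363).

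Salicylic acid genes rose for 2 of 22 (14 adjusted over the list alone, median 1.55, adjusted p = 1.34e-09, adjusted p = 0.484 with an estimated correlation), the hydroxylase genes DLO1 (5.59) and DMR6 (AT5G24530, 2.69), with ICS1 at 1.62 (adjusted p = 0.131, and 0.0426 without rpt2a-2 systemic Pma replicate 2). In the list of systemic acquired resistance 1 of 10 genes rose (4 adjusted over the list alone, median 2.81, or 2.29 with genes of 0 to 3 counts at their bound, adjusted p = 0.00923, adjusted p = 0.574 with an estimated correlation), AED1 (3.46). FMO1 (adjusted p = 0.198) was at least 5.34-fold higher, a bound that rested on replicate 1 (0.374, 0.0355 and 0.0357 CPM in the Pma libraries), and ALD1 (adjusted p = 0.0839) had a ratio of 140 (47.4 to 681), and neither passed. The ALD1 ratio rested on replicate 1, since the 3 Pma libraries were at 11, 0.107 and 0.322 CPM, and the gene passed without replicate 2 or 3 of that group (adjusted p = 0.0355 and 0.0414). Pattern-triggered immunity genes rose for 1 of 20 (4, median 0.41, adjusted p = 0.00923), WRKY53 (2.42). Higher lists with 0 genes called were the proteasome (18 adjusted over the list alone, median 0.40, adjusted p = 1.54e-10), autophagy (0, median 0.45, adjusted p = 0.000124) and senescence (1, median 0.55, adjusted p = 0.017). Lower ones were photosynthesis (0, median -0.19, adjusted p = 7.51e-05), DNA replication (0, median -0.25, adjusted p = 0.0159) and aliphatic glucosinolates (0, median -0.21, adjusted p = 0.0192). These 7 lists had adjusted p = 0.602 with an estimated correlation. Epidermis markers were lower (0 of 7 called, 2 adjusted over the list alone, median -0.37, adjusted p = 0.00785, adjusted p = 0.559 with an estimated correlation). Without rpt2a-2 systemic Pma replicate 1, DNA replication (-0.10, adjusted p = 0.928) and senescence (0.18, adjusted p = 0.273) did not pass.

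Other rises were those of CRK37 (AT4G04500, 6.02), LUP5 (5.87), the natriuretic peptide gene PNP-A (AT2G18660, 5.77) and CYP71A12 (3.32), and THI2.2 (AT5G36910), a thionin gene, fell (-1.94). Without rpt2a-2 systemic Pma replicate 1 the values were 3.57 for CRK37, 4.58 for LUP5, 3.86 for PNP-A, 3.77 for PR2, 2.53 for CRK6, 4.46 for DLO1, 2.39 for PR5, 2.84 for AED1 and 1.82 for WRKY53, so their size rested in part on that library. They were 3.95 for DMR6, 4.47 for CYP71A12, 6.46 for DLO1 and 4.29 for AED1 without rpt2a-2 systemic mock replicate 3. RPT2A (0.37) and RPT2B (0.00) did not pass (adjusted p = 0.386 and 0.996). edgeR called 274 of 18723 genes, 233 higher and 41 lower, of which 137 higher and 24 lower were shared with Col-0 (3.55 and 0.431 expected). The count was 0, 0 and 1139 without rpt2a-2 systemic mock replicate 1, 2 or 3, and 132, 518 and 1113 without rpt2a-2 systemic Pma replicate 1, 2 or 3, with 0, 0, 14, 13, 15 and 15 of 15 named calls left. There were 20 genes called with the replicate block, with 1 of the 15 named calls left (LUP5), and 1627 genes with DESeq2.

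A difference between the genotypes in the systemic response was not called for any gene. ICS1 (-0.05, SE 0.77), RPT2A (-0.01) and RPT2B (0.10) each had adjusted p = 0.999, as had PR1, FMO1 and ALD1, for which rpt2a-2 systemic mock held 1, 0 and 3 counts and no fold is given. The list test passed for higher responses in rpt2a-2 of salicylic acid (median log2 0.41, camera adjusted p = 0.00246), abscisic acid (0.58, adjusted p = 0.0322), proteasome (0.14, adjusted p = 0.0019) and flavonoid genes (1.05, adjusted p = 0.000898). It passed for a lower response of folding genes (-0.23, adjusted p = 0.0178). In these lists 0 genes were called, 0 adjusted over the list alone, and adjusted p was 0.95 with an estimated correlation. Guard cell markers were higher (0.35, adjusted p = 0.00587, adjusted p = 0.776 with an estimated correlation, 0 called and 0 adjusted over the list alone). Tryptophan and camalexin genes were lower (-0.40, adjusted p = 4.11e-06, adjusted p = 0.686 with an estimated correlation, 0 called and 2 adjusted over the list alone). Without rpt2a-2 systemic Pma replicate 1, salicylic acid (0.21, adjusted p = 0.964), abscisic acid (0.05, adjusted p = 0.608), proteasome (0.01, adjusted p = 0.201) and flavonoid lists (0.30, adjusted p = 0.328) did not pass. edgeR called 0 of 18723 genes, with 666 at an unadjusted p under 0.05, and DESeq2 called 0, while 48 genes were called without rpt2a-2 systemic mock replicate 3.

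rpt2a-2 against Col-0 in systemic mock leaves again gave higher proteasome genes, 30 of 53 (45 adjusted over the list alone, median log2 0.86, camera adjusted p = 2.43e-47, adjusted p = 0.487 with an estimated correlation). RPT6B stood at 115 ± 11.4 against 28.1 ± 2.16 CPM (edgeR log2 2.03, SE 0.23, adjusted p = 0.00453), with PBB2 at 1.79 and PAE1 (AT1G53850) at 1.29. NAC103 was higher (4.88), as were PMZ (AT3G28210), a zinc finger gene (5.99), and AT4G05380, a nucleoside triphosphatase family gene (5.98). Defence lists were lower without a called gene: pathogenesis-related (3 lower adjusted over the list alone, median -1.70, adjusted p = 0.000242), salicylic acid (0, -0.79, adjusted p = 4.97e-05) and cysteine-rich receptor-like kinases (0, -1.05, adjusted p = 0.0014). Genes of systemic acquired resistance were lower as well (0, -1.44, or -1.33 with genes of 0 to 3 counts at their bound, adjusted p = 0.0304, and 0.054 with library size alone). These 4 lists had adjusted p = 0.66 with an estimated correlation.

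PR1 had 1 count in rpt2a-2 against 5.44 ± 4.6 CPM in Col-0 (ratio 443 lower, counting interval 79 to 17500) and did not pass (adjusted p = 0.163). Neither did ICS1 (-0.05, adjusted p = 0.979), FMO1 (at least 2.48-fold lower, adjusted p = 0.474) or ALD1 (ratio 3.31, 0.794 to 19.4, adjusted p = 0.867). Folding genes were lower (0 of 13 called, 0 adjusted over the list alone, median -0.41, adjusted p = 0.000242, adjusted p = 0.737 with an estimated correlation), as were abscisic acid genes (0 and 0 of 14, -0.69, adjusted p = 0.00387, adjusted p = 0.786 with an estimated correlation). Markers of xylem (0 of 6 called, 5 adjusted over the list alone, 0.53, adjusted p = 0.000173) and epidermis (0 of 7, 1, 0.24, adjusted p = 0.0304) were higher, both with adjusted p = 0.66 with an estimated correlation. The clock gene CCA1 (AT2G46830) was higher (1.07, adjusted p = 0.0478), as was SWEET11 (0.82, adjusted p = 0.0474), but both calls ended whichever of the 6 libraries was left out. Called were 177 of 18723 genes, 119 higher and 58 lower (67.2% higher, but 49.1% with DESeq2 and 25.1% without rpt2a-2 systemic mock replicate 3), of which 81 higher and 17 lower were shared with local mock leaves (1.9 and 0.615 expected). The count was 38, 10 and 14 without Col-0 systemic mock replicate 1, 2 or 3 and 58, 42 and 483 without rpt2a-2 systemic mock replicate 1, 2 or 3, and 4 of 11 named calls held in each such fit.

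rpt2a-2 against Col-0 after systemic Pma completed the set. Proteasome genes were higher for 37 of 53 (46 adjusted over the list alone, median log2 1.03, camera adjusted p = 8.05e-59). They included RPT6B (161 ± 65.4 against 29.4 ± 1.69 CPM, edgeR log2 2.46, SE 0.23, adjusted p = 0.00124), RPN8B (AT3G11270, 2.08) and PAE1 (1.72). NAC103 (4.92), PMZ (5.12) and MBP1 (AT1G52040), a myrosinase-binding protein gene (3.49), were higher. LRX3 (AT4G13340), a leucine-rich repeat extensin gene, was lower (-1.74). Tryptophan and camalexin genes were lower without a called gene (8 of 12 adjusted over the list alone, median -0.44, adjusted p = 3.36e-07), and this list and the proteasome list had adjusted p = 0.275 with an estimated correlation. Also lower were folding (0 called, 9 of 13 adjusted over the list alone, -0.66, adjusted p = 2.65e-09), systemic acquired resistance (0, 1 of 10, -0.93, adjusted p = 0.00104) and pathogenesis-related genes (0, 1 of 11, -1.26, adjusted p = 0.000107). Markers of xylem (0, 0 of 6, 0.34, adjusted p = 0.00153) and epidermis (0, 3 of 7, 0.19, adjusted p = 0.00217) were higher, and these 5 lists had adjusted p = 0.399 with an estimated correlation.

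Salicylic acid genes (0 called, 0 adjusted over the list alone, -0.26, adjusted p = 0.0442, adjusted p = 0.898 with an estimated correlation) and cysteine-rich receptor-like kinases (0 and 0, -0.18, adjusted p = 0.0484, adjusted p = 0.744 with an estimated correlation) were lower, but neither passed with RLE (adjusted p = 0.0593 for both). Flavonoids were higher (0 called, 6 of 12 adjusted over the list alone, 1.17, adjusted p = 0.000669, adjusted p = 0.67 with an estimated correlation). PR1 (-2.97), ICS1 (-0.10), FMO1 (-4.03) and ALD1 (-1.21) did not pass (adjusted p = 0.323, 0.972, 0.102 and 0.717). Without rpt2a-2 systemic Pma replicate 1 all 4 passed as lower, at -5.30 (adjusted p = 0.0402), -1.31 (0.0264), -6.01 (0.025) and -5.34 (0.00175), while flavonoids (0.22, adjusted p = 0.257) and xylem markers (0.26, adjusted p = 0.053) did not. The FMO1 value depends on the prior count, with few counts left in rpt2a-2. edgeR called 159 of 18723 genes, 143 higher and 16 lower (89.9% higher), against 956 without rpt2a-2 systemic Pma replicate 1 (54% higher), 72 without Col-0 systemic Pma replicate 2, 100 with the replicate block and 557 with DESeq2 (64.1% higher). MBP1 and LRX3 lost their calls in such fits, without Col-0 systemic Pma replicate 1 (adjusted p = 0.114) and without its replicate 2 (adjusted p = 0.187) among others.

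**Figure D3:**
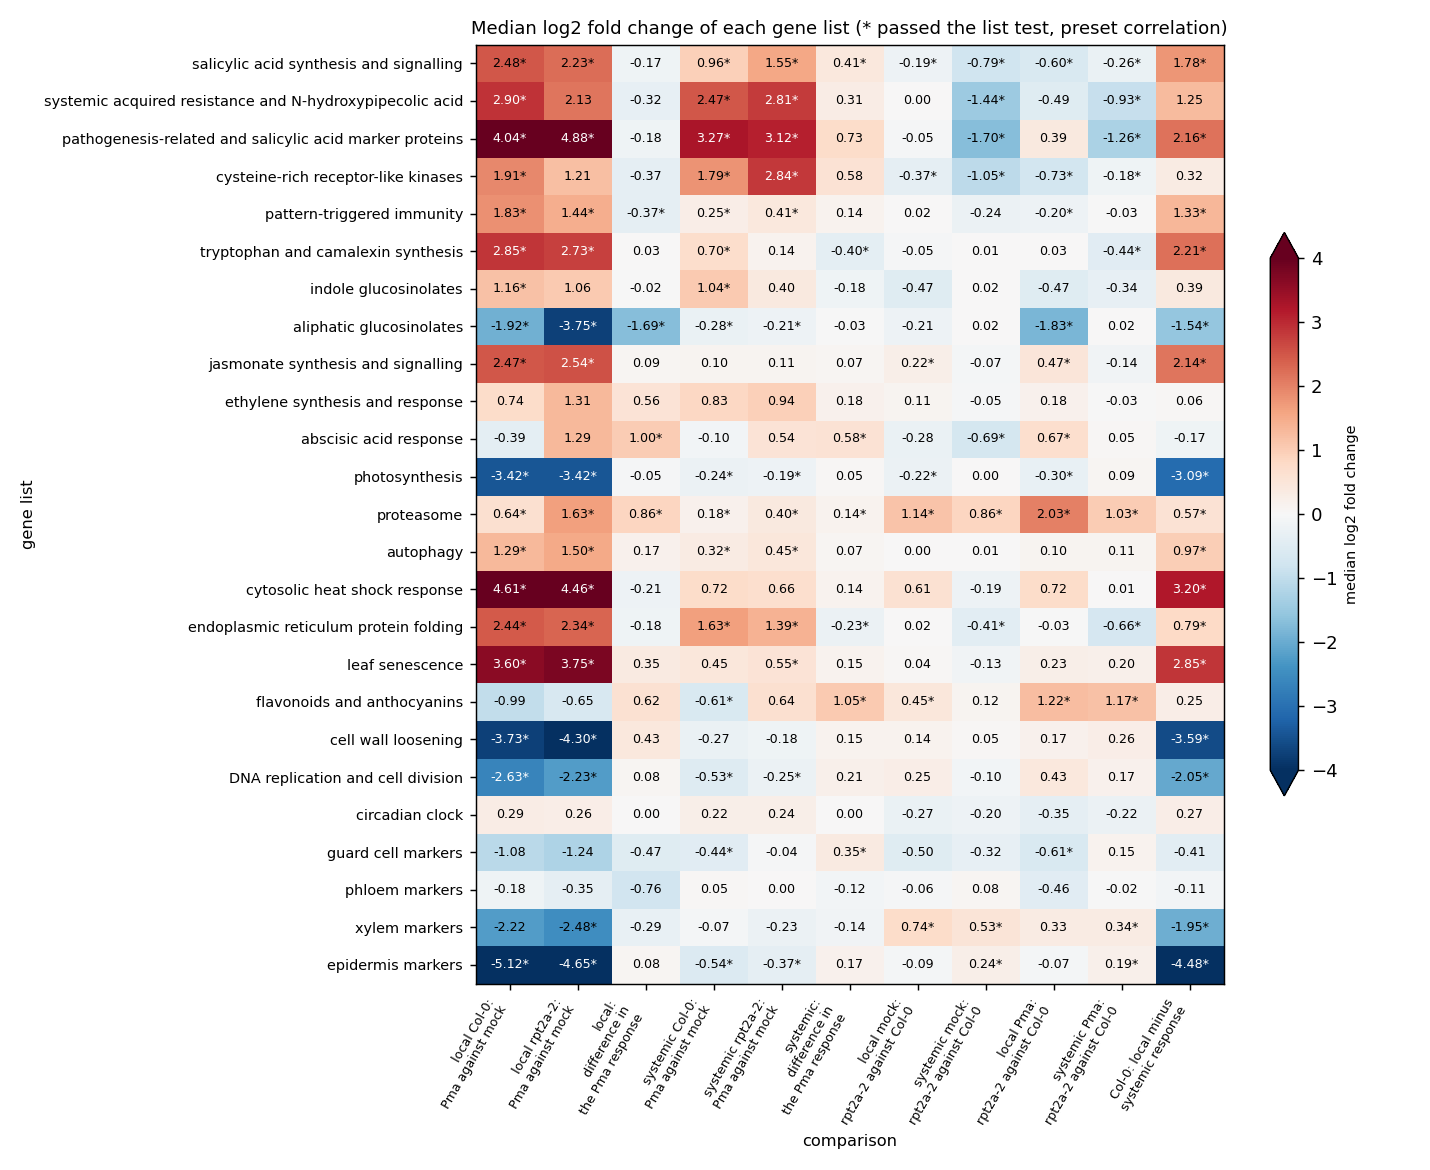
Median log2 fold change of 25 gene lists (vertical axis) in 11 comparisons (horizontal axis) on a colour scale from -4 to 4, with asterisks for lists that passed the camera test with a preset correlation. The proteasome list was higher in rpt2a-2 in the 4 genotype comparisons, with medians of 1.14, 0.86, 2.03 and 1.03.

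The local and the systemic response of Col-0 were compared with each Pma group set against its own mock. PR1 rose by 4.96 more on the log2 scale (SE 1.52, edgeR adjusted p = 0.00968) and FMO1 by 5.97 more (adjusted p = 0.0409), whereas ICS1 (0.95, adjusted p = 0.204), ALD1 (2.6, adjusted p = 0.429) and RPT2B (0.16, adjusted p = 0.38) did not pass. CYP79B2 (3.74), JAZ5 (AT1G17380, 5.38), TPS10 (11.17), NPR1 (1.19), RPT2A (0.85), BIP2 (AT5G42020, 1.5) and CNX1 (1.12) had higher local responses. LHCB5 (AT4G10340), a light-harvesting antenna gene, fell from 9210 ± 1060 to 630 ± 34.3 CPM in local leaves and stood at 9380 ± 757 and 7910 ± 239 CPM in systemic leaves (-3.62, adjusted p = 1.14e-10). LTP1 (-7.36), the cold-response gene COR15A (AT2G42540, -4.43) and MYB29 (-4.40) also fell more in local leaves, and KAT1 differed by 2.98.

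Higher local responses passed for tryptophan and camalexin (11 of 12 genes, median 2.21, camera adjusted p = 2.61e-06), jasmonate (21 higher and 2 lower of 28, 2.14, adjusted p = 7.43e-07) and senescence (8 of 12, 2.85, adjusted p = 6.93e-05). A lower one passed for photosynthesis (47 of 47, -3.09, adjusted p = 1.23e-29). These 4 had adjusted p = 0.253 with an estimated correlation. Pattern-triggered immunity (15 of 22, 1.33, adjusted p = 8.1e-05) was higher and cell wall loosening (8 lower and 1 higher of 11, -3.59, adjusted p = 0.0137) lower, both with adjusted p = 0.392 with an estimated correlation. Salicylic acid (11 of 22, 1.78, adjusted p = 0.000806), pathogenesis-related (7 of 11, 2.16, adjusted p = 0.0344, and 0.0546 with library size alone), proteasome (37 of 53, 0.57, adjusted p = 3.33e-08) and heat shock lists (8 of 15, 3.20, adjusted p = 0.00763) were higher. DNA replication (12 lower and 1 higher of 15, -2.05, adjusted p = 0.0137) and xylem markers (6 of 6, -1.95, adjusted p = 0.0353) were lower. These 6 had adjusted p = 0.631 with an estimated correlation. Folding (7 of 13, 0.79, adjusted p = 0.015) was higher and aliphatic glucosinolates (10 of 15, -1.54, adjusted p = 0.0093) lower, both with adjusted p = 0.636 with an estimated correlation. Autophagy (11 of 16, 0.97, adjusted p = 0.000272) had adjusted p = 0.545 and epidermis markers (6 of 7, -4.48, adjusted p = 0.000509) adjusted p = 0.277 with an estimated correlation. Numbers adjusted over the list alone were the same except for the proteasome (38) and DNA replication (13 lower). Among defence lists, systemic acquired resistance (4 higher and 1 lower of 10, 1.25), indole glucosinolates (2 and 1 of 9, 0.39) and ethylene (3 and 1 of 12, 0.06) did not pass (adjusted p = 0.373 each), nor did cysteine-rich receptor-like kinases (2 and 1 of 13, 0.32, adjusted p = 0.724).

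In that comparison edgeR called 10823 of 19776 genes, 4809 with a higher and 6014 with a lower local response. FMO1 did not pass without Col-0 local mock replicate 3 (adjusted p = 0.0606), Col-0 local Pma replicates 2 or 3 (0.0513 and 0.0543), Col-0 systemic mock replicates 1, 2 or 3 (0.108, 0.0541 and 0.164) or Col-0 systemic Pma replicate 3 (0.0542). The experiment is a batch in the labels, differs in the second infiltration and may differ in the leaves sampled, so these cannot be told apart.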

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

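Of the tests in this part, those of scaling and of an infected-like state for the proteasome genes, of library depth for replicate 1 and of a stronger response of all genes were chosen only after the result was seen. Replicate 1 was picked after its values were seen. The other results below were picked because the effect of Pma differed between genotypes, or between local and systemic leaves of Col-0, by a test of the difference itself.

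Proteasome genes were higher in rpt2a-2 in each genotype comparison, and their median response to local Pma was 0.86 higher than in Col-0. With an estimated correlation this list passed in local mock leaves alone (adjusted p = 0.0233). Tables argued against scaling, since the lowest median over 4 genotype comparisons and 2 other scalings was 0.82, and against an infected-like state of the mock plants, since the higher of the 2 mock medians of pathogenesis-related genes was -0.05 and not the rise of at least 4 which that state needed. A variant acting only on neighbours of RPT2A was argued against by 41 genes called higher in local mock leaves with identifiers of other chromosomes, against 5 on chromosome 4. A second variant in rpt2a-2 that acts on other chromosomes stayed open, because the series holds 1 mutant line. A feedback from reduced RPT2A onto genes of the same complex may account for the pattern, a biological hypothesis from the genotype that no complemented line tested.

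Replicate 1 of rpt2a-2 systemic Pma stood apart from replicates 2 and 3, with 280 genes at least 4 times higher than in both, against 8 and 4 such genes for replicates 2 and 3. Depth was argued against by a ratio of at most 1.03 between the 3 totals. A median position of 1.26 over 35 genes (Col-0 at 0, rpt2a-2 at 1) argued against a wrong genotype or mixture with Col-0. Directly infiltrated leaves were argued against as source of all 280 genes. They needed a median of 39.1% of their local level (quartiles 11.5 and 190). The 1081 genes induced locally reached 1.66% (quartiles 0 and 7.53), a ratio of 0.0425. For the 153 of them apart no share was taken, so carry-over stayed open. Replicate 1 had 140 genes lower by the 4-fold measure. A stronger systemic response is a hypothesis for part of it. Yet 4 flavonoid genes were apart, a list lower after Pma without replicate 1 (median -0.5). Bacteria in upper leaves or a differing second infiltration stayed open, untested.

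Aliphatic glucosinolate genes had a median response to local Pma that was lower in rpt2a-2, by -1.69, a call lost with an estimated correlation (adjusted p = 0.917). A stronger response of all genes was argued against by a slope of 0.953 of rpt2a-2 on Col-0 changes, and scaling by medians of -1.77 (RLE) and -1.86 (library size alone). Counts near the floor were argued against by a median of -1.69 over the 13 members with at least 1 CPM in every group, all 13 of them below 0. A stronger loss of these transcripts in infected rpt2a-2 leaves is therefore a hypothesis that may hold, found and tested on the same data. Whether it follows from RPT2A or from another variant of the line was not tested.

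For local Pma the genotypes differed in 1637 genes. Other lists with a called difference were abscisic acid (1.00) and pattern-triggered immunity (-0.37), both lost with an estimated correlation (adjusted p = 0.917). Differences in response of single genes (log2, rpt2a-2 minus Col-0) were 0.57 for RPT2A, 1.09 for RPT2B, 1.63 for PBB1, 1.41 for PBE2 and 1.35 for PBC2. They were -2.06 for MYB28, -1.90 for CYP83A1, -1.35 for UGT74C1, -0.81 for RBOHF, 0.78 for ABI1, 1.03 for ABI2, 2.72 for VSP2, 1.01 for EPS1 and 1.41 for NYC1. Further values were 3.71 for AT1G15180, 4.03 for AT1G10790, -3.85 for CSLD5, -0.78 for CRK10, 0.66 for NBR1 and 0.95 for FKF1. The fitted values of PRXCA, a peroxidase gene (4.25), and AT4G36700, a cupin gene (-4.75), depend on the prior count. Among 100 splits of the 12 local libraries 6 called as many genes as the real split (1637, with 5706 in the highest other split). The other 5 of these splits exchanged mock libraries between genotypes but no Pma libraries. They measured the genotype itself, a structure of the samples, so the count says nothing about chance for the difference in response.

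For systemic Pma 0 genes and 7 lists had a called difference between the genotypes, and 0 of the 7 lists passed with an estimated correlation (adjusted p of 0.686 to 0.95). Salicylic acid, abscisic acid, proteasome and flavonoids did not pass without rpt2a-2 systemic Pma replicate 1. Medians were 0.41 for salicylic acid, -0.40 for tryptophan and camalexin, 0.58 for abscisic acid, 0.14 for the proteasome, -0.23 for folding in the endoplasmic reticulum, 1.05 for flavonoids and 0.35 for guard cell markers. Since the real split called 0 genes, each of 100 splits of the systemic libraries called at least as many, an outcome fixed in advance that says nothing about chance. The highest other split called 1717 genes, and which libraries it exchanged was not examined.

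Local and systemic responses of Col-0 differed in 10823 genes. Of the 16 lists with a called difference 0 passed with an estimated correlation. List medians (log2, local minus systemic) were 1.78 for salicylic acid, 2.16 for pathogenesis-related proteins, 1.33 for pattern-triggered immunity, 2.21 for tryptophan and camalexin, 2.14 for jasmonate, 0.57 for the proteasome, 0.97 for autophagy, 3.20 for heat shock, 0.79 for folding and 2.85 for senescence. Lower ones were -1.54 for aliphatic glucosinolates, -3.09 for photosynthesis, -3.59 for cell wall loosening, -2.05 for DNA replication, -1.95 for xylem and -4.48 for epidermis markers. Single genes were RPT2A at 0.85, PR1 at 4.96, FMO1 at 5.97, TPS10 at 11.17, CYP79B2 at 3.74, JAZ5 at 5.38, BIP2 at 1.5, CNX1 at 1.12, NPR1 at 1.19 and KAT1 at 2.98. Lower ones were LHCB5 at -3.62, LTP1 at -7.36, COR15A at -4.43 and MYB29 at -4.40. Fitted values that depend on the prior count were 9.56 for JAZ8, 13.77 for BSMT1, 9.87 for the carotenoid dioxygenase CCD8 and -8.99 for GER3. Of 40 splits 3 called as many genes as the real one (10823, with 12572 in the highest other split). The other 2 exchanged mock libraries between experiments but no Pma libraries, so they measured the experiment itself and say nothing about chance for the difference in response.

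For comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real split called 15020 genes for local Pma in Col-0 and 15067 in rpt2a-2, and the highest other split 0 in each, so 1 split was as large in both. Real and highest other values were 482 and 0 for systemic Pma in Col-0 (1 split), 274 and 1 in rpt2a-2 (1 split), 533 and 3 between genotypes in local mock leaves (1 split), 177 and 0 in systemic mock leaves (1 split) and 6751 and 0 after local Pma (1 split). After systemic Pma 2 splits were as large, with 159 real calls and 1098 in the split that exchanged Col-0 systemic Pma replicate 3 with rpt2a-2 systemic Pma replicate 1, several times the real count, which points to a structure of the samples.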

How the results depend on the processing

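Scaling by library size alone, and the list tests without rpt2a-2 systemic Pma replicate 1, were chosen only after the result was seen. The other alternatives were RLE scaling, no filter beyond 1 count, 1 CPM in 3 libraries, a replicate block, DESeq2, all 24 libraries or only the 6 compared in the fit, an estimated correlation for the lists, and leaving out each replicate. A group left with 2 libraries shared its estimate of spread with the others.

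Counts of called genes stayed within 1.5 times the reported count under each alternative run for the local Pma response of Col-0 (14104 to 15550) and of rpt2a-2 (14081 to 15643), for the genotypes after local Pma (5006 to 7464) and for the local against the systemic response of Col-0 (9862 to 11419). RLE and 1 CPM in 3 libraries left the 11 counts within that limit.

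The genotype difference in the local response, 1637 genes, was 2638 with DESeq2 and 876 (without Col-0 local Pma replicate 3) to 1764 (without Col-0 local Pma replicate 1) without single replicates. For local mock leaves, 533 became 1097 with DESeq2, 330 with only the 6 libraries, and 265 (without Col-0 local mock replicate 1) to 574 without single replicates. For the systemic response of Col-0, 482 became 283 with library size alone, 204 with the replicate block, 1580 with DESeq2, 1605 with all 24 libraries and 2647 with only 6. Without single replicates it was 12 (Col-0 systemic mock replicate 3) to 849 (Col-0 systemic Pma replicate 3). For the systemic response of rpt2a-2, 274 became 416 with library size alone, 169 without a filter, 20 with the block, 1627 with DESeq2, 2122 with all 24 libraries and 0 with only 6. Without single replicates it was 0 (rpt2a-2 systemic mock replicates 1 or 2) to 1139 (replicate 3 of that group). The genotype difference in the systemic response was 0 in each alternative except without rpt2a-2 systemic mock replicate 3, so the range was 0 to 48. For systemic mock leaves, 177 became 114 with library size alone, 86 with the block, 798 with DESeq2, 636 with all 24 libraries and 1017 with only 6. Without single replicates it was 10 (Col-0 systemic mock replicate 2) to 483 (rpt2a-2 systemic mock replicate 3). For the genotypes after systemic Pma, 159 became 100 with the block, 557 with DESeq2, 352 with all 24 libraries and 2 with only 6. Without single replicates it was 72 (Col-0 systemic Pma replicate 2) to 956 (rpt2a-2 systemic Pma replicate 1). DESeq2 made 20.7% false calls in the systemic self-test against 2.99% for edgeR. The cause was not tested.

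Of 126 list results that passed, 123 kept their side of the threshold and their direction with RLE, 118 with library size alone and 126 with the block, but 1 with an estimated correlation, the proteasome list in local mock leaves (adjusted p = 0.0233). With the block 2 more lists passed. Without rpt2a-2 systemic Pma replicate 1, 22 of 30 were kept, 6 no longer passed and 2 turned. In the genotype difference of the systemic response, the test direction turned to lower for the proteasome list (median 0.01, adjusted p = 0.201), and for abscisic acid (median 0.05, adjusted p = 0.608). Flavonoids in the systemic response of rpt2a-2, a list that had not passed (median 0.64, adjusted p = 0.346), turned to -0.50 and passed as lower (adjusted p = 0.00573). For these 3 the alternative differed from the reported test in that library alone.

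Of 212 named gene results that passed, 208 still passed with RLE, 184 with the block and all 211 that could be compared with DESeq2, and 1232 of 1512 fits without single replicates kept their call. No named call turned direction in these fits. Named genes that had not passed did turn. RPT2B in the local response of Col-0 (-0.05) was at 0.05 with RLE and 0.06 with DESeq2, and RPT2B in the systemic response of rpt2a-2 at 0.00 with the block. With the block ALD1 was at -0.07 and -0.77 in the local and systemic genotype difference, and PR1 at -0.12 in local mock leaves. FMO1 was at -0.34 with DESeq2 in the systemic genotype difference. Without single replicates RPT2B ranged from -0.10 to 0.14 (local Col-0) and from -0.06 to 0.08 (systemic rpt2a-2), and RPT2A from -0.04 to 0.59 (systemic rpt2a-2) and from -0.41 to 0.21 (systemic genotype difference). In the local genotype difference PR1 ranged from -1.42 to 0.27, FMO1 from -2.10 to 1.03 and ALD1 from -1.17 to 0.99. In the systemic one ICS1 ranged from -1.24 to 0.38, FMO1 from -1.71 to 1.08 and ALD1 from -3.78 to 3.40. In local mock leaves PR1 ranged from -0.69 to 1, FMO1 from -1.55 to 1.57 and ALD1 from -1.74 to 0.42. ALD1 in systemic mock leaves ranged from -4.61 to 0.43, and ICS1 after systemic Pma from -1.31 to 0.32. FMO1 and ALD1 stood at few counts in mock leaves, so that these values depend on the prior count. The cause was not tested.

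Within each experiment libraries of the same number were not closer to each other than others, and pairing across the experiments was not tested. Their residual correlations ran from -0.23 to 0.20 in the local experiment, with 3 of 18 above 0.1, and from -0.30 to 0.40 in the systemic one, with 5 of 18. Counts limited genes at 0 to 3 counts in a group, where 2 of 16 list medians shifted, by up to 0.52. The spread between replicates limited systemic leaves more, where the self-test recovered 63% of changes of 2-fold, and 23% for the genotype difference.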

Other observations

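The genes below were chosen after their values were seen, and no test of an explanation was made for them.

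IREG2 (AT5G03570), iron regulated 2, held 2 counts in rpt2a-2 local mock and 0 in the other 3 rpt2a-2 groups. Its ratio in local mock leaves was 745 lower (95% counting interval 206 to 6160), and it was at least 328-fold lower in systemic mock, 193-fold in local Pma and 183-fold in systemic Pma leaves. In Col-0 it stood at 16.9 to 20.5 CPM in local mock and 9.39 to 10.9 CPM in systemic mock leaves. After Pma it was at 7.77, 8.08 and 0 CPM in Col-0 local replicates 1, 2 and 3 and at 9.86, 7.74 and 0 CPM in Col-0 systemic replicates 1, 2 and 3. RPT2A was at 246 CPM in Col-0 local Pma replicate 3, against at most 99.4 CPM in local rpt2a-2 libraries, and at 107 CPM in Col-0 systemic Pma replicate 3, against at most 42.1 CPM in systemic rpt2a-2 libraries. The call in local mock leaves (adjusted p = 0.0198) ended in 5 of the 6 fits without a library (0.0598 to 0.0961).

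AT2G40955, an uncharacterized protein gene, had the reverse pattern. It held 1 count in Col-0 local mock (ratio 685, counting interval 122 to 27100) and 0 in the other Col-0 groups, where rpt2a-2 was at least 197-fold higher in systemic mock, 51.9-fold in local Pma and 156-fold in systemic Pma leaves. The call in systemic mock leaves (adjusted p = 0.00751) ended without Col-0 systemic mock replicate 2 (0.054). AT1G71370, a gene of the DEAD-box helicase family, was higher in rpt2a-2 by ratios of 680 (122 to 26900) in local mock, 165 (45.5 to 1370) in systemic mock and 553 (98.8 to 21900) in systemic Pma leaves, and by log2 7.12 in local Pma leaves (42.6 ± 3.44 against 0.304 ± 0.228 CPM). AT4G33380, annotated as a tRNA methylthiotransferase, was lower in rpt2a-2 in local mock (log2 -3.39), systemic mock (-2.92), local Pma (-5.47) and systemic Pma leaves (-3.47), and the 4 calls held without each replicate.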
